A study of Homo sapiens with 10 samples.

How the data were processed

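Acinar and ductal cells sorted from human exocrine pancreas were profiled by CUT&Tag for H3K4me1 (3 libraries per cell type) and H3K27ac (2 libraries per cell type). The values analysed here are 4 deposited peak lists, 1 per cell type and mark, each combining the libraries of its group. Per the submitters' processing notes, the genome build was hg38 and the tools named were Bowtie2 2.4.4, MACS2 2.2.7.1 and deepTools 3.5.1; their settings are not given in the sources used here. Each peak has a start and end, the authors' fold enrichment (a ratio) at the summit, and the authors' deposited −log10 p and −log10 q. The lowest −log10 q was between 1.31 and 1.36 in every list. These peak scores are the authors' own, and were used here to rank, filter or describe peaks within a list. Pileups and backgrounds recovered from them were also compared between lists, for depth, enrichment and strong regions. Per-library values were not used here, so donors, days and the spread between libraries cannot be assessed, and the labels do not say which libraries come from the same donor.

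Depth was read from the scores. MACS2 derives fold and p from a whole-number read pileup at the summit and a local background. Solving both together gave a whole-number pileup for 100% of peaks in each list, within 0.002 of the deposited −log10 p. The lowest background of a list was taken as its genome-wide coverage, which was 26.6% higher in the ductal than in the acinar H3K27ac list and 1.79% higher for H3K4me1. A peak at that background needed a pileup of at least 6 reads in the acinar and 7 in the ductal H3K27ac list, and of 8 in both H3K4me1 lists; a higher local background needed more. A region below such a limit is not listed, so a gene listed at 0 can still carry a weaker mark.

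Peaks on the 22 autosomes and chromosome X were used. Overlaps were counted from 1 shared base, and chance overlap is the mean of 100 circular shifts of the other list within chromosomes. Shares have Wilson 95% intervals, and Jaccard indices have intervals from 1000 bootstrap draws of 5 Mb blocks. Gene coordinates came from NCBI RefSeq for GRCh38 (19974 protein-coding genes), in a table with gene starts and ends but no strand. The design had set windows around transcription start sites. Because the start site could not be told from the other gene end, each window instead covered 10 kb on both sides of both ends (20 to 40 kb in all), and distal regions were those over 1 kb from either end of every protein-coding gene. A planned count of sequence motifs in cell-type-only regions was not run, because no genome sequence was used here.

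For each gene and mark, the percentage of the window covered was computed per list, and differences are acinar minus ductal in percentage points. A gene is called above or below the central range when its difference lies outside the central 95% of all protein-coding genes. That range was -6.93 to 2.94 points for H3K27ac, and -6.69 to 6.35 points for H3K4me1; this criterion was set after the data were seen and describes these lists, not the conditions. The 15 gene lists, with 253 genes of which 252 matched (PNLIPRP2 did not), the tests and the main alternatives were fixed before the data were examined. Each list's median difference was placed among 10000 random lists of the same size, matched on mean coverage, as a description of these libraries. Genes were named by a rule: the 12 largest differences in covered length per direction and mark, the 3 largest per direction in each list, 8 anchor genes, and genes in the 10 largest joined domains; other list members are named as examples. Genes on chromosome Y and XIST were left out, and a few named genes and 1 locus are not reported here.

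Alternatives were an overlap of 50% of the region, peaks with −log10 q of 5 or more, equal list lengths, a distal limit of 2.5 kb, and windows of 5 and 25 kb. A window over the whole gene span plus 10 kb, and thinning of the ductal lists to the acinar background coverage, were added, as were all alternatives for H3K4me1 gene lists, after the data were seen. The procedures were tested on simulated data. In simulated H3K27ac lists of 20 genes, all lists raised by 2, 4 or 8 percentage points were found (100%), as were 4.5%, 5% and 3% of unchanged lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.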

Results

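The human exocrine pancreas holds acinar cells, which make and secrete digestive enzymes, and ductal cells, which line the tubes that carry the secretions and add bicarbonate and fluid. Both cell types were isolated from exocrine tissue by flow sorting and profiled by CUT&Tag, in which an antibody directs a transposase to chromatin that carries a chosen histone mark. H3K4me1 marks enhancers whether or not they are active, and H3K27ac marks active enhancers and promoters. The series holds 10 libraries: 3 acinar and 3 ductal libraries for H3K4me1, and 2 acinar and 2 ductal libraries for H3K27ac. The deposited peak lists analysed here hold 1 combined list per cell type and mark, so no difference below has a replicate check and no p-value is given. On the autosomes and chromosome X, the lists held 68621 acinar and 90342 ductal H3K27ac regions, and 153372 acinar and 172954 ductal H3K4me1 regions. The background read coverage recovered from the peak scores was 1.29 in the acinar and 1.63 in the ductal H3K27ac list. For H3K4me1 it was 2.504 and 2.549.

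The first comparison asked which genes carry active chromatin in one lineage and not in the other, measured as the percentage of a window around both ends of each gene that H3K27ac regions cover. The digestive enzyme genes stood on the acinar side. PRSS1, which encodes cationic trypsinogen (chromosome 7, 142749472 to 142753072, hg38), had 20.3% of its window covered in the acinar list and 3.55% in the ductal list. CTRB2, a chymotrypsinogen gene, had 15.6% in acinar cells and was listed at 0 in ductal cells. The same held for CLPS, encoding colipase, at 14.8% and 0, and for PNLIP, encoding pancreatic lipase, at 10.2% and 0. On the ductal side, KRT19, a keratin of ductal epithelium (chromosome 17, 41523617 to 41528308), had 6.43% in acinar and 20.5% in ductal cells, and CFTR, the chloride and bicarbonate channel of the duct (chromosome 7, 117480025 to 117668665), had 0.550% and 14.4%.

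The digestive enzyme list held 27 genes that could be matched, some of which, such as REG1A, GP2 and ERP27, do not encode enzymes. Of the 27 genes, 25 had more H3K27ac coverage in acinar cells and 22 lay above the central 95% of all 19974 protein-coding genes. The list's median difference, acinar minus ductal, was 8.33 percentage points, above the medians of all 10000 random lists of the same size and mean coverage. Neighbouring members such as CELA3A and CELA3B have overlapping windows, so the same regions can count for both. Genes of the random lists were drawn independently, so the spread of those lists can be too narrow. A region lay within 1 kb of a gene end in the acinar list alone for 20 of the 27 genes, among them CPA1, CPB1, CTRC, CELA2A and AMY2B. The 5 genes inside the central range were CELA3A, CELA3B, CTRL, PLA2G1B and ERP27. For CELA3A the covered percentage was 8.89% in acinar and 13.0% in ductal cells, and for ERP27 it was 13.0% and 11.002%. CELA3B passed to the ductal side, with a difference of -10.1 points, when the window was narrowed to 5 kb.

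The acinar transcription factor list, of 7 genes, had a median difference of 5.83 points, again above all 10000 random lists. The median fell to 2.58 points with peaks of −log10 q 5 or more and to 2.55 points in the 25 kb window, and rose to 7.09 points with the whole gene span. PTF1A, a determinant of acinar identity (chromosome 10, 23192312 to 23194245), had 9.44% in acinar cells and was listed at 0 in ductal cells. Its partner gene RBPJL had 8.11% and 0.894%. BHLHA15, which encodes the secretory regulator MIST1, had 9.36% and 2.26%, and XBP1, a regulator of the secretory pathway, had 14.1% and 8.22%. These were the 4 members above the central range. NR5A2 was covered about equally, at 7.53% and 8.93%. GATA4 and CREB3L1 also stayed inside the central range, GATA4 neither in the 25 kb window (2.55 points) nor with the whole gene span (7.84 points).

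Genes of the endoplasmic reticulum and secretory pathway had a smaller difference on the acinar side. Their median difference was 0.615 points over 20 genes, while the median of all protein-coding genes was -0.973 points, and it exceeded all 10000 random lists. The list median fell to 0.192 points with peaks of −log10 q 5 or more, 0.263 in the 5 kb and 0.234 in the 25 kb window, and rose to 0.911 with equal list lengths. PDIA2, a pancreas-enriched disulphide isomerase gene, had 5.95% in acinar cells and was listed at 0 in ductal cells. SEL1L, which acts in degradation of misfolded proteins, had 7.56% and 2.89%, and HERPUD1 had 11.2% and 7.65%. DNAJC3 and SEC61B also lay above the central range, DNAJC3 not in the 5 kb window. SYVN1 went the other way, at 9.17% and 13.9%, inside the central range.

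Of 22 ductal epithelial genes, 21 had more H3K27ac coverage in ductal cells, and the median difference of -4.96 points lay below all 10000 random lists. KRT19, CFTR, CA2, SPP1, PROM1 and SCTR lay below the central range. CA2, encoding carbonic anhydrase 2, was listed at 0 in acinar and had 11.5% in ductal cells. SPP1, encoding osteopontin, was listed at 0 and had 10.8%, and SCTR, encoding the secretin receptor, had 4.06% and 13.3%. KRT7, another duct keratin gene, was covered alike, at 10.01% and 10.24%. SLC4A4, encoding a sodium bicarbonate cotransporter, was the 1 member with more acinar coverage, at 3.07% and 2.16%, and passed to the acinar side in the 5 kb window (4.705 points).

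**Figure D1:**
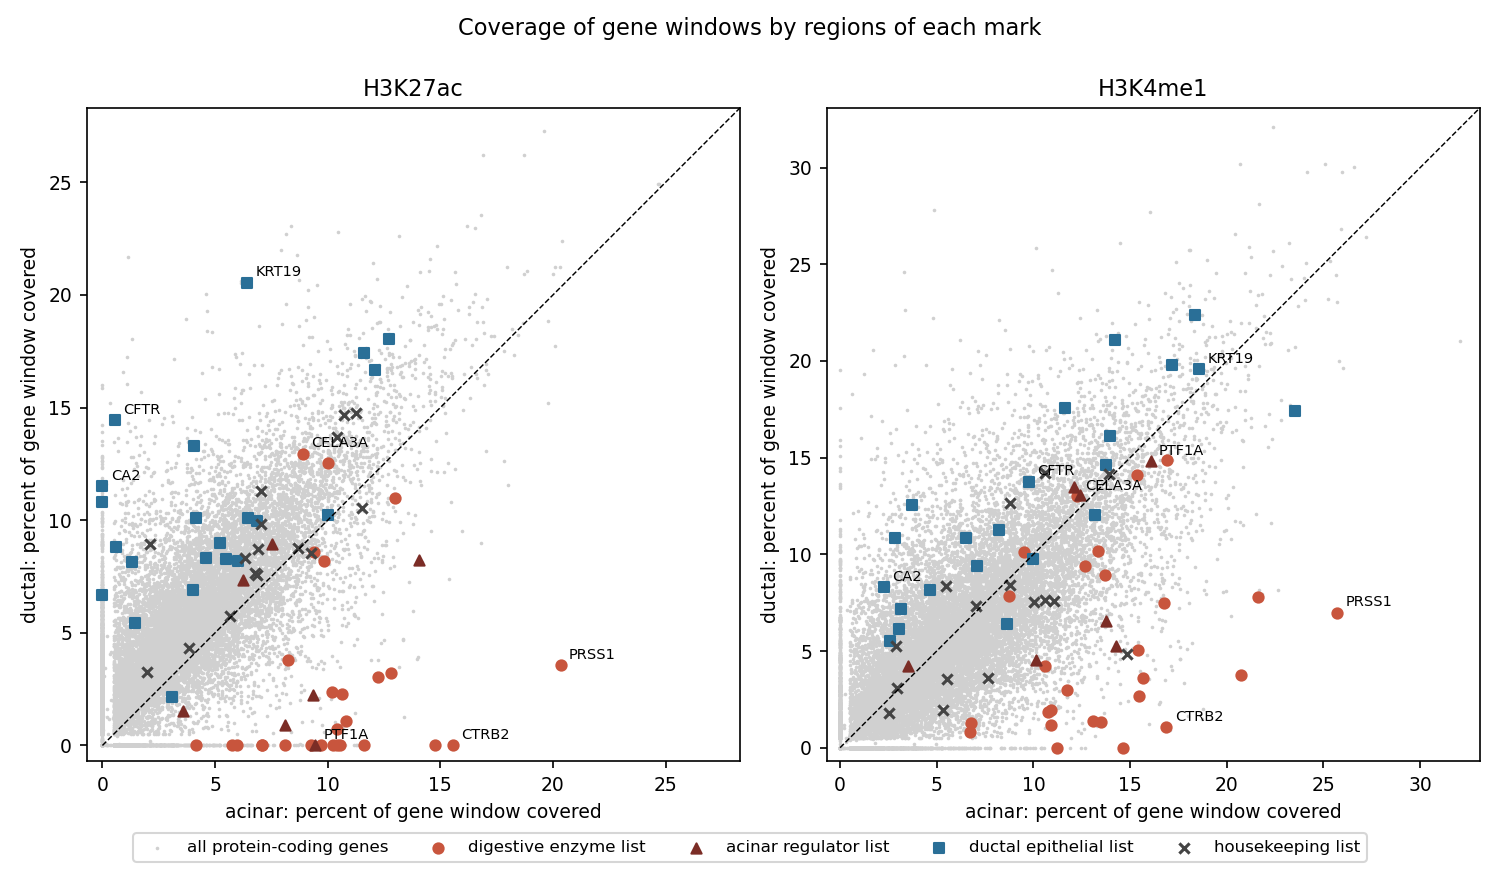
Percentage of each gene's window covered by regions in the acinar list (horizontal) and the ductal list (vertical), for H3K27ac (left) and H3K4me1 (right); each point is 1 gene, there are no error bars because there is 1 list per cell type, and the dashed line marks equal coverage. In the H3K27ac panel most digestive enzyme genes lie at or near 0 on the ductal axis, while KRT19 (6.43% acinar, 20.5% ductal) and CFTR (0.550%, 14.4%) lie far above the line; in the H3K4me1 panel PTF1A and KRT19 lie near it.

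The transcription factor genes usually assigned to ducts formed a list of 9. SOX9, a ductal and progenitor factor, had 9.769% in acinar and 8.997% in ductal cells. GLIS3, listed at 0 in acinar and at 7.73% in ductal cells, was the 1 member below the central range, and left that side when the whole gene span was used. The list's median difference of -1.99 points was at percentile 45.3 of random lists. Among 13 factors of the wider pancreatic programme, PDX1 had 2.17% and 11.97%, NKX6-1 had 1.55% and 9.73%, and PROX1 had 5.16% and 16.7%, all below the central range. PDX1 was not past the limit when only peaks with a −log10 q of 5 or more were used, nor NKX6-1 in the 25 kb window. HNF4A, HNF4G and FOXA1 were covered alike, and the list's median of -2.91 points was at percentile 13.6. That median moved to -0.860 points, at percentile 97.1, in the 5 kb window. With equal list lengths it was -1.76 points, at percentile 31.7, and with peaks of −log10 q 5 or more -3.29 points, at percentile 5.33.

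Mucin and gastric-type genes had a median difference of -2.54 points, at percentile 4.39, which is inside the central 95% of random lists. TFF2, a trefoil factor gene, was listed at 0 in acinar and had 8.85% in ductal cells, and was inside the central gene range under 4 alternative settings. AGR2 went the other way, at 9.67% and 5.65%, inside that range in the 5 kb window. Genes of Notch and Hippo signalling had a median of -2.88 points, at percentile 3.72. Within that list AMOTL2, a YAP target, had 10.9% and 18.2%, and HEYL, a Notch target, had 8.38% in acinar and 0.588% in ductal cells. AMOTL2 was no longer past the limit after the ductal list was thinned to the acinar depth. AP-1 and inflammatory genes had a median of -1.88 points, at percentile 65.3. LIF (0.855% and 11.4%) and CXCL1 (2.07% and 10.6%) were below the central range, LIF not in the 5 kb window. FOS (12.4% and 8.14%) was above it, though neither in the 5 kb nor in the 25 kb window.

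Endocrine, mesenchymal and endothelial marker genes carried little H3K27ac in either list. The median coverage of 25 endocrine genes was 0 in both lists, and INS, GCG, SST and IAPP were listed at 0 in both. Mesenchymal genes had medians of 0 in acinar and 0.670% in ductal cells, and DCN, LUM and THY1 were listed at 0 in both. Endothelial genes had medians of 0.728% and 0.281%; VWF, KDR and FLT1 were listed at 0 in both, whereas ESAM had 0.929% and 16.6%. Immune genes had medians of 1.34% and 3.63%. Regions lay in the windows of 14 of the 18 in ductal and 12 in acinar cells. Within 1 kb of a gene end, 13 of the 18 had no region in either list. Of all 19974 protein-coding genes, 3935 were at 0 in the ductal and 5095 in the acinar list. PTPRC, CD163 and LAPTM5 were listed at 0 in both, and CD68 had 14.8% and 18.7%. The housekeeping genes had medians of 6.97% and 8.74%, and all 16 had a region near a gene end in both lists. Genes of unrelated lineages, such as MYOD1 and FLG, had medians of 0 in both. None of these 6 lists left the central 95% of random lists. For endocrine and unrelated-lineage genes this was fixed in advance. Most of their members (16 of 25 and 11 of 15) had equal coverage, being at 0 in both lists, and were matched to such genes. Both limits of their random lists were therefore 0. The upper limit was also 0 for mesenchymal, endothelial and immune genes.

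Among all protein-coding genes, the 12 largest acinar excesses in covered length included 7 genes of the digestive enzyme list. The others were MGST1 (11.2% in acinar and 0 in ductal cells), a glutathione transferase gene, FAM174B (11.3% and 0), MAT1A (10.7% and 0.758%), ANKRD62 (8.88% and 0) and the readthrough gene ARPIN-AP3S2 (13.4% and 4.70%). The 12 largest ductal excesses included BDKRB2, a bradykinin receptor gene (1.08% and 17.2%), GYPC (0 and 16.0%), FRAS1 (4.65% and 19.3%), BARX2, a homeobox gene (0 and 12.8%), ITIH5 (0 and 12.6%) and KCNJ16, a potassium channel gene (1.23% and 14.0%). FRAS1 and ITIH5 were inside the central range when the whole gene span was used. Across the genome 3151 genes had more H3K27ac coverage in acinar cells, 13474 had more in ductal cells and 3349 had equal coverage. Mean coverage was 3.38% and 4.76%, so gene differences are read against a shift toward the ductal list. A further limit concerns the digestive enzyme list. Several genes of that list, such as CTRB1 and CTRB2 or REG1A and REG1B, have closely similar copies between which short reads can be misplaced.

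H3K4me1 was compared in the same windows. The digestive enzyme list again stood on the acinar side, with a median difference of 8.97 points and 16 of 27 genes above the central range. PRSS1 had 25.7% in acinar and 6.99% in ductal cells, and PNLIP had 14.6% and was listed at 0. Secretory pathway genes had a median difference of 3.94 points, and both lists exceeded all 10000 random lists. The secretory median was 1.98 points, at percentile 99.85, in the 25 kb window and 4.83 points in the 5 kb window. Ductal epithelial genes had a median of -3.05 points, at percentile 0.04 (not past the limit in the 5 kb window), with AQP1, SPP1 and PKHD1 below the central range. The 13 wider pancreatic factors had a median of -2.80 points, at percentile 1.14, with PDX1 (8.09% and 15.2%) and GATA6 (9.71% and 16.4%) below the range. The other 11 lists lay between percentiles 5.74 and 87.8.

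Several regulators and duct genes outside the central H3K27ac range stayed inside the H3K4me1 range, as did most such genes. Of 500 genes above the H3K27ac range, 318 stayed inside the H3K4me1 range and 182 lay above it. Of 500 below, 320 stayed inside, 179 lay below and 1 above. The upper limits differ, at 2.94 points for H3K27ac and 6.35 for H3K4me1, so these counts do not compare the size of differences. The 500 genes above had median H3K27ac of 7.66% in acinar and 2.63% in ductal cells, and median H3K4me1 of 11.3% and 5.51%. For the 500 below, the medians were 2.21% and 11.6% for H3K27ac, and 8.66% and 13.7% for H3K4me1. Because most such genes stayed inside the H3K4me1 range, the genes named next are examples and not exceptions. BHLHA15 (14.3% H3K4me1 in acinar and 5.27% in ductal cells), XBP1 (13.8% and 6.58%) and SPP1 (2.85% and 10.9%) lay outside both ranges. PTF1A had 16.1% H3K4me1 coverage in acinar and 14.8% in ductal cells. KRT19 had 18.6% and 19.6%, CFTR had 9.77% and 13.8%, and LIF had 11.8% and 16.1%. Around PTF1A the acinar list held 5 H3K27ac regions and the ductal list 0, while H3K4me1 regions numbered 8 and 6. The acinar H3K27ac regions at 23188740 to 23189459 and 23195025 to 23195348 overlapped no ductal H3K4me1 region. Those at 23183247 to 23183661, 23186982 to 23187208 and 23199069 to 23199452 did overlap one. Similar counts therefore do not mean that all the same positions are marked. Across CFTR and 10 kb on each side there were 1 acinar and 39 ductal H3K27ac regions. The H3K4me1 regions there numbered 15 and 54. The genes with the largest ductal excess in H3K4me1 included MYMK (4.85% and 27.8%), WNT7B (4.81% and 22.2%) and EDN3 (6.22% and 21.1%). Those with the largest acinar excess included STIMATE (22.6% and 8.17%), ATP4A (17.8% and 3.36%) and RTN4R (16.5% and 2.24%), STIMATE not past the limit in the 5 kb window. Over all genes, 9552 had more H3K4me1 in acinar and 8661 in ductal cells.

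The next comparison asked how far the lineages share their marked regions. Of the acinar H3K27ac regions, 45142 overlapped a ductal one (65.8%, Wilson 95% interval 65.4 to 66.1) and 23479 were acinar-only. Of the ductal H3K27ac regions, 43194 overlapped an acinar one (47.8%, 47.5 to 48.1) and 47148 were ductal-only. Lists shifted along the chromosomes shared 3.29% and 2.47%. For H3K4me1, 56620 regions were acinar-only and 75344 ductal-only, with 63.1% (62.8 to 63.3) and 56.4% (56.2 to 56.7) shared. The shared length over the length covered by either list was 0.372 (0.366 to 0.378, block bootstrap) for H3K27ac and 0.377 (0.372 to 0.382) for H3K4me1. Acinar-only H3K27ac regions were more often distal, that is over 1 kb from any protein-coding gene end, at 94.4% against 72.3% of shared regions, and ductal-only ones at 91.4% against 72.9%. Cell-type-only H3K27ac regions were also narrower than shared ones. Median widths were 306 against 493 bp in acinar and 372 against 660 bp in ductal cells. They also scored lower, with a median −log10 q of 5.42 against 10.9 and of 6.52 against 15.9. A wider region overlaps a gene end or another region more readily, and width was not matched here. In the strongest 10% of each H3K27ac list by −log10 q, 95.2% of acinar and 88.7% of ductal regions were shared, and in the weakest 10% they were 38.6% and 19.4%. When both lists were limited to equal numbers of their best peaks, the counts were 27759 acinar-only and 30324 ductal-only regions, and equal lengths bring these counts close by construction. With only peaks of −log10 q 5 or more there were 15143 acinar-only and 36983 ductal-only regions.

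**Figure D2:**
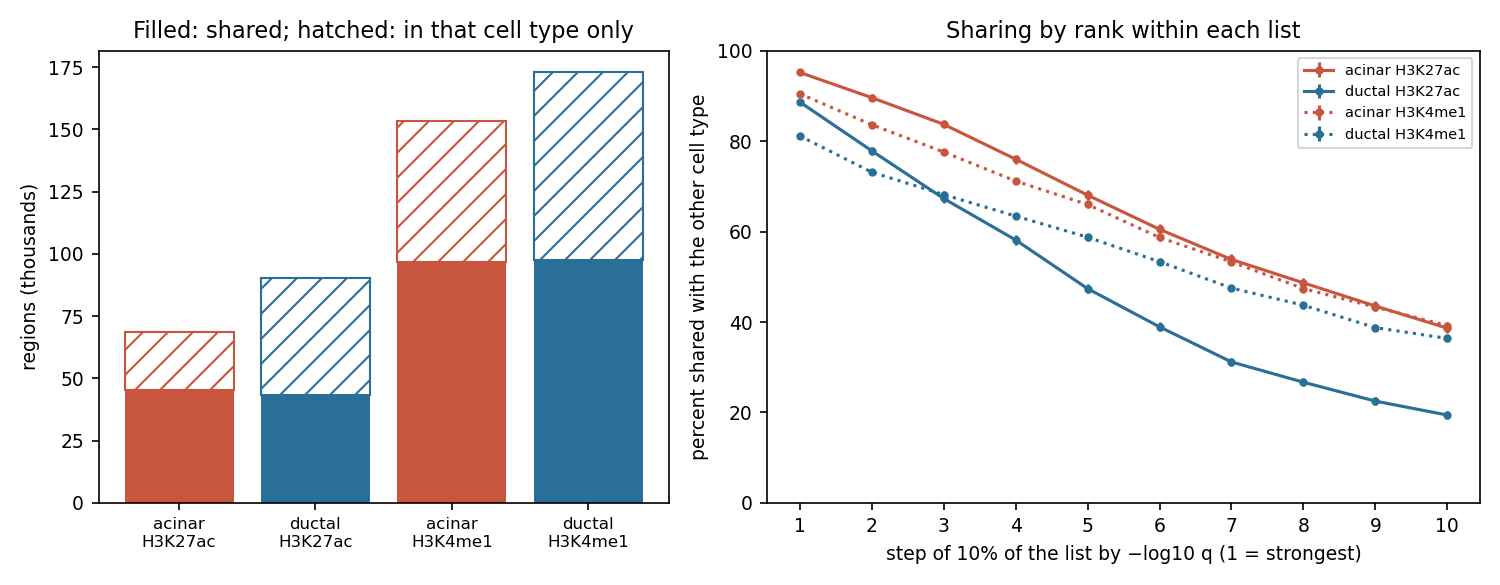
Left, number of regions in each list, with the shared part filled and the part found in that cell type alone hatched. Right, percentage of regions shared with the other cell type by rank in the list, in steps of 10% by the deposited −log10 q, with Wilson 95% intervals that are mostly smaller than the points; for H3K27ac sharing goes from 95.2% to 38.6% in the acinar list and from 88.7% to 19.4% in the ductal list.

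The last comparison asked what state regions acetylated in one lineage have in the other. Of 22175 distal acinar-only H3K27ac regions, 77.6% (77.0 to 78.1) carried H3K4me1 in acinar cells and 38.0% (37.4 to 38.7) carried it in ductal cells, against 4.98% for shifted regions. Of 43094 distal ductal-only H3K27ac regions, 87.3% (86.9 to 87.6) carried H3K4me1 in ductal cells and 44.5% (44.0 to 45.0) in acinar cells, against 4.77%. Distal H3K27ac regions shared by both cell types carried H3K4me1 in the other cell type in 90.6% and 93.2% of cases. In their own cell type these shared regions carried it in 92.4% of acinar and 91.2% of ductal cases. Cell-type-only regions were narrower and weaker than shared ones and were not matched to them. How much of the gap goes with width and strength was therefore not tested. Of all distal H3K4me1 regions, 34.5% (34.3 to 34.8) in acinar and 43.6% (43.3 to 43.8) in ductal cells carried H3K27ac in the same cell type. Of the 81871 distal acinar H3K4me1 regions that ductal cells share, 35.01% carried H3K27ac in both, 9.23% in acinar cells alone, 22.6% in ductal cells alone and 33.2% in neither. These intervals cover counting error only.

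Neighbouring H3K27ac regions were also joined over short gaps and the joined domains ranked by covered length within each list. The PRKCH locus on chromosome 14 was among the 10 first domains of both lists. The acinar list further held domains at MEIS1 (covered to 11.8% in acinar and 12.3% in ductal cells), GALNT2 (10.3% and 7.34%) and PELI2 (10.1% and 4.81%). The ductal list held domains at EXT1 (7.52% in acinar and 12.2% in ductal cells), SMAD3 (12.6% and 13.1%) and NEDD4L (7.70% and 12.02%). Its domain on chromosome 9 from 4064737 to 4278149, inside the span of GLIS3 (3824127 to 4490465), was covered to 12.1% in ductal and 1.49% in acinar cells.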

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

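All tests below were chosen, or their bounds reset, after the result was seen. Peaks on unplaced contigs lie outside the comparisons above. They numbered 474 in the acinar and 406 in the ductal H3K27ac list, and 596 and 515 in the H3K4me1 lists.

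Ductal-only H3K27ac regions were 2.01 times as many as acinar-only ones (47148 against 23479). Ductal-only regions with −log10 p of 20 or more numbered 5173, which is 2.19 times the acinar-only regions at the score that the lower acinar depth would give (2361), and this argues against read depth as the whole cause for strong regions. Acinar summits at 12523 shared regions at gene ends were 0.712 times the highest overlapping ductal ones, a choice that can lower the ratio. This value holds the depth ratio of 0.790 and leaves 0.902 for enrichment. At 32619 other shared regions the ratio was 0.753, nearer to the depth ratio. Most cell-type-only regions are distal, so 0.712 may overstate weaker enrichment for them, and the count was not repeated at 0.753. Scaled by 0.712, the strong regions were 1.43 times the acinar-only ones (3622) with recomputed scores and 1.69 times with scores multiplied by 0.712. Both ratios thus kept a ductal excess. At this factor even the lowest expected acinar score of the strong regions stayed above the lowest listed −log10 p of 3.24. The median expected score was 16.9. These values argue against depth and weaker acinar enrichment together as the whole cause for strong regions. A part in the excess stays open, because the ratio fell and 0.712 is a median, with a 25th percentile of 0.541. For weaker regions, thinning the ductal pileups removed only 1.83% of ductal regions for depth and 5.61% for depth and enrichment together. Weaker ductal-only regions then still numbered 40641 against 21363 acinar-only ones for depth, and 37969 against 20645 for both together. Little of the excess thus went with the thinning. It kept a peak by its summit score alone, however, while no list holds peaks under 200 bp. Thinning may therefore keep too many peaks, and both explanations stay open for weaker regions. A difference between the cell types or between donors stays open and was not tested.

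ESAM, an adhesion gene of endothelium, and ROBO4 carried H3K27ac in ductal cells (16.6% and 7.25% of the window) and little in acinar cells (0.929% and 0.705%). Endothelial cells in the ductal sort would bring the other endothelial genes too; 7 of the 14 list genes were at 0 in the ductal list, VWF, KDR and FLT1 among them, while PECAM1 had 4.03% and SOX18 2.84%, and with no endothelial list to give the level each would need, this stays open. Of the ductal covered length in the ESAM window, 24.2% lay within 1 kb of the gene, which with that margin takes 38.3% of the window. A bound set earlier ignored that share, so regions of a neighbouring gene are neither shown nor excluded; the neighbours VSIG2 (1.09% acinar and 13.5% ductal) and MSANTD2 (1.55% and 12.4%) have overlapping windows. A ductal difference in these loci stays open and was not tested.

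CELA3A, CELA3B, CTRL, PLA2G1B and ERP27 carried ductal H3K27ac, with a median of 11.002% of the window. By the highest summit pileups anywhere in their windows, scaled for depth, acinar cells in the ductal sort would have to make up at least 59.8% of it to bring this. That share would list all 14 of the 27 digestive genes that were at 0 in the ductal list, with a median of 53.7 reads. This argues against acinar cells as the whole cause of the ductal coverage in these windows, although a smaller share is not excluded. The highest summits can belong to a neighbouring gene, so regions at the genes themselves were not tested apart. The part of the ductal covered length within 1 kb of the gene ran from 7.66% (CTRL) to 59.6% (ERP27). A count made first, 4 at 0 among the 10 genes with the most acinar coverage (ERP27 included), had not decided the question. Of the ductal covered length in the 5 windows, 41.2% lay within 1 kb of the genes, which with that margin take 43.3% of the windows, so neighbouring genes stay open (CELA3A and CELA3B are each other's only one within 10 kb). A ductal role of some of these regions was not tested.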

How the results depend on the processing

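No paired analysis was possible because each cell type and mark has 1 combined list, and no library was left out for the same reason. The alternatives with the gene span, the thinning, those of the H3K4me1 lists and, for single genes, the 5 kb and 25 kb windows were chosen after seeing the data. No called value changed direction: of 222 alternative values of the counts, shares and list medians, 197 stayed on their side or within their spread. Of 1050 values for named genes, 997 kept their class, 30 left the outer range, 23 entered it and 0 went from 1 outer range to the other. Of the 23, GRB10 changed sign, from -0.61 to 3.45 points with the gene span. Thinning could hardly move gene values, as it left 88690 of 90342 ductal H3K27ac and 172830 of 172954 ductal H3K4me1 regions. Of its 175 values, 173 kept their class. The 222 values include the H3K27ac medians of endocrine and unrelated-lineage genes, whose main outcome was fixed in advance. Both counts therefore overstate stability. With only peaks of −log10 q 5 or more, acinar-only H3K27ac regions numbered 15143, the H3K4me1 Jaccard index was 0.366, and H3K4me1 in the other cell type was found at 40.3% of distal acinar-only and 43.3% of distal ductal-only H3K27ac regions. With equal list lengths, ductal-only H3K27ac regions numbered 30324, the H3K27ac Jaccard index was 0.385, those shares were 39.2% and 48.4%, and 38.4% of distal ductal H3K4me1 regions carried H3K27ac. With an overlap of 50% of the region, H3K27ac was found at 26.5% of distal acinar and 36.5% of distal ductal H3K4me1 regions, and H3K4me1 in the other cell type at 35.8% and 42.1% of the cell-type-only regions. With a distal limit of 2.5 kb, 34.8% and 43.9% of distal H3K4me1 regions carried H3K27ac; after thinning the ductal value was 43.0%. A stricter overlap lowers the shares by construction; the cause of the other shifts was not tested. The Notch and Hippo list passed to the ductal side of the random lists with the 25 kb window (-2.72 points) and with the gene span (-4.17 points), and the cause was not tested. All other H3K27ac lists stayed on their side of the limit under each alternative. For H3K4me1, the digestive, secretory and wider factor lists kept their call throughout, and ductal epithelial genes lost theirs in the 5 kb window (-1.01 points). With the 25 kb window and the gene span, calls arose for acinar factors (2.69 and 3.46 points) and Notch and Hippo genes (-1.56 and -1.60 points). With the 25 kb window alone they arose for mesenchymal (-0.922 points) and endothelial genes (-1.076 points). At the lowest background, regions under 6 to 8 reads are beyond the depth of these lists.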

Other observations

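Many HOX and NKX genes carried H3K4me1 in both cell types without H3K27ac in either; the gene families below were chosen by symbol after the values of some members were seen, and no test was run. All 39 HOX genes were listed at 0 for H3K27ac in both lists, and 37 of them held H3K4me1 regions in both, with medians of 9.63% of the window in acinar and 9.89% in ductal cells. HOX genes lie close together in clusters, so their windows overlap and the same regions are counted for several genes. For 14 NKX genes the medians were 6.44% and 9.62%, and 11 of them had H3K4me1 in both lists with H3K27ac at 0 in both. In the 7 other regulator families counted (such as PAX, TBX and SOX), 29 of 67 genes were at 0 for H3K27ac in both lists and 26 of these held H3K4me1 in both. Of 390 olfactory receptor genes, which are expressed mainly in the nose, 325 were at 0 for H3K27ac in both lists and 9 of those held H3K4me1 in both. Across all 19974 protein-coding genes, 3340 were at 0 for H3K27ac in both lists and 1169 of these held H3K4me1 in both.

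Endocrine genes were split into factor genes and others after their values were seen, and no test was run. Of 10 endocrine transcription factor genes, all 10 held H3K4me1 regions in both lists, with medians of 8.13% in acinar and 10.8% in ductal cells, and 2 and 3 of them held H3K27ac. NKX2-2 had 13.83% and 12.49%, and ISL1 had 14.4% and 14.7%, both with H3K27ac at 0 in both lists. The 15 other endocrine genes, such as INS and GCG, had medians of 2.04% and 1.955%, with H3K4me1 regions at 8 of them in acinar and 11 in ductal cells. TWIST1, a mesenchymal factor gene (15.4% and 16.3%), and SOX17, an endothelial one (13.3% and 19.3%), also held H3K4me1 without H3K27ac.

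Some genes with H3K27ac in 1 cell type alone carried much H3K4me1 in the other. Of 500 genes above the central H3K27ac range, 143 were listed at 0 in ductal cells, and 5 of these had at least 10% H3K4me1 coverage in ductal cells: PTF1A, ITPKA, GPER1, RNF133 and REG1A. Of 500 genes on the ductal side, 102 were at 0 in acinar cells and 8 had at least 10% H3K4me1 there, among them BMP4 (16.4% H3K4me1 in acinar and 15.5% in ductal cells), HES4 (11.9% and 20.2%), ID4 (10.9% and 12.7%) and TFPI2 (10.1% and 9.18%). For comparison, 17.2% of all protein-coding genes had at least 10% in ductal and 17.7% in acinar cells, and of genes at 0 for H3K27ac in that cell type 3.20% and 2.73% did. Median H3K4me1 was 2.36% in ductal cells for the 143 genes and 4.99% for all genes, and in acinar cells 4.23% for the 102 genes and 5.11% for all genes. All 12 genes with the largest ductal excess in H3K4me1 were listed at 0 for acinar H3K27ac, as were 5095 of all 19974 protein-coding genes. The 12 were picked for less H3K4me1 in acinar than in ductal cells. The 2 marks often overlap, so the absence of acinar H3K27ac there is not a separate result.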
